A study of Homo sapiens with 6 samples.

How the data were processed

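MRC5 cells, human lung fibroblasts, were cultured for 6 days with cigarette smoke condensate (CSC, the particulate fraction of smoke) at 40 ug/ml or with the solvent DMSO, per the labels' protocols. Cells were between passages 22 and 28 and grew in medium with 10% serum. The labels give this range for every sample and no passage per sample, so a difference in passage between the groups cannot be excluded. Total RNA of 6 samples, 3 per group, was converted to Cy3-labelled cRNA from 100 ng per sample and hybridised to 1-colour Agilent arrays, 1 sample per array. The labels number the replicates 1 to 3 in each group and do not say whether these came from separate cultures, so p-values measure the spread between these samples, which may be technical.

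Per the file headers, the authors scanned the arrays at 5 microns per pixel and extracted them with Agilent Feature Extraction 11.5.1.1, while the submitters' processing notes list version 10.7.3.1. The deposited scanner files hold spot intensities on a linear scale. The processed intensity used here was background-subtracted and detrended within each array by that software, per the file headers, with no scaling between arrays. The deposited value table holds log2 values for 22412 probes. Its scale and centring are not stated. Set against the scanner values of the same arrays after a 75th percentile shift, each of its 6 columns correlated with r of at least 0.999, and each probe was centred on the mean of the DMSO arrays, to a median absolute deviation of 4.0e-08. The column medians were 0.09, 0.08 and 0.0048 for CSC replicates 1 to 3 and 0.01, 0.01 and -0.01 for DMSO replicates 1 to 3. It had 6 missing values, and the rule by which its probes were chosen is not given in the sources used here. It served as an alternative to the scanner files.

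Control spots and spots flagged as outliers were left out, and no spot was saturated on any array. Each array had 43118 non-control spots for 34127 probes, of which 999 were spotted 10 times each, and spots of 1 probe were averaged. Values were log2 of the processed signal minus the 75th percentile of the array. Probes were kept if well above background on at least 3 of the 6 arrays, which left 24940. The scanner files carry accessions in place of gene names. These were matched without versions to a RefSeq gene table of assembly GRCh38.p14, which gave 1 symbol to 27349 probes (80.1%) and none to 6778. Among probes with a curated RefSeq transcript accession, 27246 of 27679 matched. The grid of the arrays was annotated on hg19, per the file headers, so no coordinates of the table are given. A gene name was represented by its probe with the highest mean signal, which gave 19901 names tested, 16067 of them with a symbol. Of the 4139 names with more than 1 kept probe, 1119 had probes with fold changes of differing sign, and 15 had probes that passed the test in both directions.

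Differences between CSC and DMSO were tested, two-sided, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all names and a threshold of 0.05. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. For a gene not well above background on any array of 1 group, the fold is an approximate lower bound. It is the mean of the brighter group over a floored mean of the dimmer group. The floor on each array is the lowest signal among probes well above background, or the gene's own signal where higher. Probes brighter than that lowest signal can still miss the call, so the true fold may lie below the bound. In total 33 gene lists, with 845 entries of which 829 were on the array and 790 were measured, were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists. Camera sets a list against all other genes. Some lists share genes, so their results are not independent. The tests were repeated with the correlation estimated for each list, and with fry, which tests whether the genes of a list move on balance in 1 direction. A count adjusted over the list alone uses the Benjamini-Hochberg adjustment among the members of that list. A list that did not shift is one that camera did not pass at the preset correlation, and fry could differ.

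The genes named were chosen by a fixed rule. It takes the 10 largest rises and 10 largest falls by fitted log2 fold change with an adjusted p under 0.05 and non-overlapping groups that carry a symbol and are well above background on all 3 arrays of the higher group. It adds up to 4 genes of each list with the lowest p, and CYP1A1, CYP1B1, AHRR, NQO1, HMOX1, CDKN1A, GDF15, MKI67, COL1A1, ACTA2, IL6 and MMP1. No probe carried the name AHRR here. Metallothionein, AKR1C, GSTM, HSPA1 and CCL3 probes can bind RNA of near-identical family members, so values of these genes are not specific to 1 member.

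The replicate numbers coincide with the slides, each of which carried 1 CSC and 1 DMSO array, and replicates 1 and 2 were scanned on 1 day and replicate 3 on another. Across genes, the deviations from the group means of the same-numbered CSC and DMSO arrays correlated at 0.25, 0.16 and 0.66, all above 0.1, so the numbers were taken to pair the samples by the threshold set for this check. Differently numbered arrays of the same scan day correlated higher, CSC 1 with DMSO 2 at 0.35 and CSC 2 with DMSO 1 at 0.42, so for replicates 1 and 2 the deviations followed the scan day rather than the number. All pairs across scan days were negative. Deviations from a mean of 3 arrays sum to 0, so positive pairs among replicates 1 and 2 fix these signs. They also fix the positive sign of the replicate 3 pair, so none of these signs is further evidence. With these limits, a fit with the number as a block was run beside the unblocked one. The CSC array always lay at position 2 of the 2 used positions of a slide, so position and group cannot be told apart.

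The test was checked on simulated data for the comparison of CSC with DMSO, with 19896 genes at the observed means. The spreads were those that limma had shrunk toward a common value, so shares at the observed spreads may differ. Of 67 genes changed 1.5-fold, 11.9% were recovered, of 67 changed 2-fold 62.7%, and of 66 changed 4-fold 92.4%. Of the calls, 9 (7.5%) fell on unchanged genes. All 3 lists raised by 0.5 on the log2 scale passed camera, and 0 of the 30 other lists did. The simulated genes varied independently, so this cannot show how camera treats lists whose genes move together. The mitosis list, for example, had an estimated correlation of 0.39 in the data. The share of genes changed was also far smaller than the 24.5% called in the data. With 3 arrays per group, the number of arrays limits the precision.

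The gene lists, the rule for named genes, the test and most alternatives were set before the data were examined. These alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the array median, no filter or a filter over all 6 arrays, eBayes with trend and robust estimation, the replicate block, leaving out each array, the mean over the probes of a gene, the deposited table, every probe tested, an unmoderated statistic, a 2-fold minimum and a threshold of 0.01. Normexp was run on median spot and background signals because the mean spot signal was not among the columns of the files used here. Scaling to 7 spike-in transcripts, RNAs of known amount added to each sample, and the use of scan day 1 alone were added after the data were seen.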

Results

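The series measured gene expression in MRC5 human lung fibroblasts after 6 days with cigarette smoke condensate (CSC) at 40 ug/ml, or with DMSO, on 3 arrays per group. The question was which genes differ between exposed and solvent-treated cells. The 75th percentile of the processed signal was 769, 708 and 1328 on the CSC arrays and 1146, 1065 and 1644 on the DMSO arrays of replicates 1 to 3, and 67.1% to 79.0% of spots were well above background. Arrays of the same group correlated across genes with r between 0.990 and 0.997 and arrays of different groups with r between 0.976 and 0.986. The first principal component held 57.5% of the variance and separated CSC from DMSO, and the second held 25.1% and separated replicate 3 from replicates 1 and 2. Values given below are log2 fold changes of CSC over DMSO ± SE with n = 3 arrays per group, and adjusted p-values are from limma with Benjamini-Hochberg adjustment.

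Fibroblasts exposed to CSC had lower levels of genes of mitosis (mean log2 fold change -1.58), DNA replication (-1.14) and the list of collagens and matrix assembly (-0.55) than those with DMSO (adjusted p = 0.0880 to 0.125 with an estimated correlation). Genes of the ATF4 amino acid response (1.05), which supplies amino acids under stress, and NRF2 targets (0.94), which detoxify oxidants, were higher, and so were autophagy and lysosome genes (0.54), whose mean was -0.23 with scaling to the spike-ins. In the same order these had adjusted p = 0.102, 0.0464 and 0.0880 with an estimated correlation. Among the largest rises was that of the chemokine CCL3 (an approximate bound of at least 69.4-fold with 75th percentile scaling, and a log2 fold change of 3.22 with normexp). So were those of transcripts of the kynurenine pathway enzyme KYNU (4.69 ± 0.14) and of the lysosomal glycoprotein GPNMB (4.47 ± 0.12). Transcripts of the pentraxin PTX3 (-3.48 ± 0.16), of the hyaluronan-degrading protein CEMIP (-3.44 ± 0.11) and of the collagen chain COL5A3 (-3.09 ± 0.13) were among the largest falls. Of 19901 gene names tested, 4873 (24.5%) changed, 2604 higher and 2269 lower, and 624 rose and 667 fell at least 2-fold. Of the 33 gene lists, 8 shifted up and 8 shifted down by camera, and 1 of these 16 calls, that of NRF2 targets, held with an estimated correlation. Interferon-stimulated genes lost theirs at an estimated correlation of -0.0030, below the preset 0.01, so a lost call need not reflect genes moving together. Fry gave each of these 16 lists the same direction, with adjusted p up to 0.0188. These directions are relative to the 75th percentile of each array, where the median of all genes was 0.048. It was -0.72 relative to spike-in transcripts, RNAs added in known amounts, 0.11 without a filter and 0.17 with normexp background correction. The split was 1210 higher and 1794 lower with scaling to the array median, and 253 higher and 8193 lower with scaling to the spike-ins. With the replicate number, which is also the slide, as a block, 4943 names changed (2694 higher, 2249 lower), and on scan day 1 alone 3382 changed (1621 higher, 1761 lower), while scan day 2 held 1 array per group and allowed no test. Without DMSO replicate 2 the count was 2868 (1478 higher, 1390 lower), and without DMSO replicate 1 it was 1732 for higher names. Normexp gave 2821 (1576 higher, 1245 lower).

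CCL3, a chemokine for monocytes and lymphocytes, rose at least 69.4-fold (adjusted p = 5.7e-05), and was not well above background on any DMSO array. The long non-coding RNA LINC00520 rose at least 13.3-fold, the synaptic vesicle priming gene UNC13A at least 8.10-fold, the cornified envelope gene LORICRIN at least 7.80-fold and the transporter gene SLC22A15 at least 6.69-fold, also from no DMSO array well above background. These 5 genes were selected by fitted fold change, and as lower bounds their folds give no order among them or against other rises. The bounds are approximate and hold only for the 75th percentile scaling and background subtraction used here. With normexp CCL3 (3.22), LINC00520 (1.56), UNC13A (1.38), LORICRIN (1.09) and SLC22A15 (1.06) had fitted log2 fold changes below these bounds. With scaling to the spike-ins the fitted log2 fold change of CCL3 was 5.53, against 6.30. SLC16A6, a transporter of the monocarboxylate family, rose by 4.88 ± 0.15 (29.5-fold, adjusted p = 5.7e-05). KYNU, which encodes kynureninase of tryptophan breakdown, rose by 4.69 ± 0.14 (25.8-fold), GPNMB by 4.47 ± 0.12 (22.2-fold) and the phosphatase gene DUSP26 by 4.35 ± 0.09 (20.3-fold). SPP1, which encodes osteopontin, rose by 4.81 ± 0.21, with 1 of the 3 DMSO arrays well above background. Among the leukocyte markers, which do not include CCL3 or SPP1, 2 of 12 measured genes rose, CD14 by 0.68 ± 0.12 and CD68 by 0.69 ± 0.13, and CORO1A fell by 1.11 ± 0.16 (2 and 1 adjusted over the list alone). The marker list did not shift (adjusted p = 0.672). The call of CD14 was lost with normexp (adjusted p = 0.0509, from 0.0056 over 16 alternatives), and that of CD68 with scaling to the array median (adjusted p = 0.0732, from 0.0034) and without DMSO replicate 2 (adjusted p = 0.0579). With normexp, which shrinks folds of dim probes, these 10 rises lay between 1.06 and 3.56, with SLC16A6 (3.56) and DUSP26 (3.25) above CCL3 (3.22), and all 10 kept their call.

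Among the largest falls, CORIN, which encodes a membrane protease that activates natriuretic peptide, fell 15.9-fold (adjusted p = 5.7e-05), with 2 of the 3 CSC arrays well above background. SLC7A14, of the cationic amino acid transporter family, fell by 3.61 ± 0.09 (12.2-fold), and its 3 probes ran from -3.61 to -2.30. PTX3, a pentraxin of innate immunity, fell by 3.48 ± 0.16 (11.2-fold). CEMIP fell by 3.44 ± 0.11 (10.8-fold), COL5A3 by 3.09 ± 0.13 (8.53-fold), and ACAN, which encodes the proteoglycan aggrecan, by 3.08 ± 0.15 (8.45-fold), while a second ACAN probe gave -0.14 and the mean of both -1.61. The antisense RNA PLCE1-AS1 was lower (adjusted p = 0.0028), with 1 of the 3 CSC arrays well above background. With normexp, CORIN had a value of -1.70, SLC7A14 -2.31, COL5A3 -1.89 and PLCE1-AS1 -0.79, all still past the threshold. CGA, the alpha subunit of glycoprotein hormones, fell at least 4.10-fold, the axonemal dynein gene DNAH7 at least 2.60-fold and the matrix gene ABI3BP at least 2.23-fold, with no CSC array well above background. These 3 were selected by fitted fold change, and their bounds lie below the folds of other falls, such as POSTN (6.50-fold) and CXCL1 (6.19-fold). Their bounds too hold only for the main scaling and background subtraction. With normexp the values were -0.46 for CGA, -0.073 for DNAH7 and -0.13 for ABI3BP. The calls of these last 3 genes were lost with normexp (adjusted p = 0.126 for CGA, 0.829 for DNAH7 and 0.675 for ABI3BP), and their lowest adjusted p over 15 alternatives was 5.2e-05, 4.3e-05 and 0.00016.

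**Figure D1:**
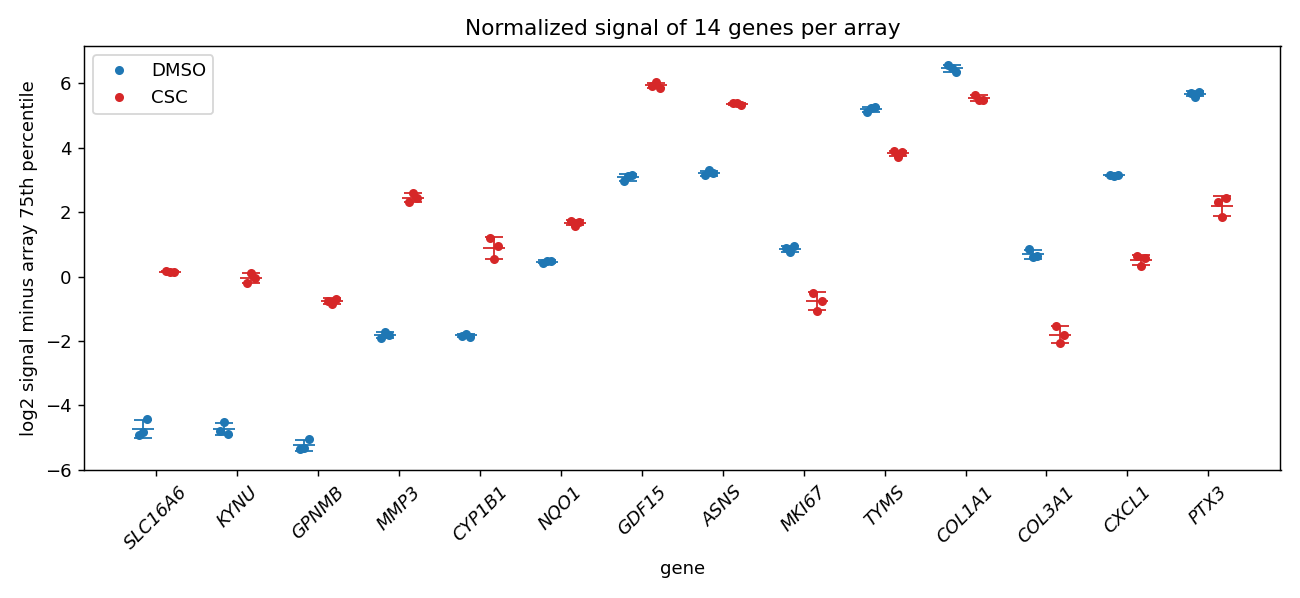
Normalized signal (log2 processed signal minus the array's 75th percentile, y axis) of 14 genes (x axis) on the 3 DMSO arrays (blue) and the 3 CSC arrays (red), with points for arrays, horizontal marks for means and bars for 1 SD. The differences between the group means run from 4.88 for SLC16A6 to -3.48 for PTX3, the smallest being -0.92 for COL1A1, and no gene drawn changes sign with scaling to the spike-ins.

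Among NRF2 targets, 21 of 29 measured genes rose and 0 fell (22 and 0 adjusted over the list alone), with a mean of 0.94 (camera adjusted p = 2.3e-11, and adjusted p = 0.0464 with an estimated correlation). They include the aldo-keto reductase genes AKR1C1 (2.17 ± 0.08) and AKR1C3 (2.08 ± 0.09), the cystine transporter gene SLC7A11 (2.01 ± 0.08), the quinone reductase gene NQO1 (1.21 ± 0.08) and the heme oxygenase gene HMOX1 (0.79 ± 0.10, adjusted p = 0.0034). The mean of the list was 0.92, 0.99 and 0.92 on slides 1 to 3 and 0.17 with scaling to the spike-ins. Among targets of the aryl hydrocarbon receptor, 7 of 15 measured genes rose and 1 fell (7 and 1 adjusted over the list alone), with a mean of 0.62, or -0.15 with scaling to the spike-ins (adjusted p = 0.0027, and adjusted p = 0.0988 with an estimated correlation). CYP1B1, a cytochrome P450 of polycyclic hydrocarbon metabolism, rose by 2.72 ± 0.17 (6.57-fold), the receptor's repressor TIPARP by 1.11 ± 0.09 and the growth factor gene EREG by 1.12 ± 0.11. CYP1A1 was dim, with mean signals of 14.9 with CSC and 15.4 with DMSO, and its difference of 0.43 ± 0.16 did not pass (adjusted p = 0.103). IL1B, the member that fell, had a value of -1.08, and it and other members that ran against their list were chosen after their values were seen.

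Of 30 measured glutathione genes, 14 rose and 1 fell (15 and 2 adjusted over the list alone), with a mean of 0.26, or -0.51 with scaling to the spike-ins (adjusted p = 0.0029, and adjusted p = 0.0988 with an estimated correlation). The membrane glutathione transferase gene MGST1 rose by 1.26 ± 0.08, the glutathione-degrading enzyme gene CHAC1 by 1.24 ± 0.13 and GCLC, the catalytic subunit of the rate-limiting enzyme of synthesis, by 0.89 ± 0.11. GGT5, a gamma-glutamyltransferase that cleaves glutathione outside the cell, fell by 2.28 ± 0.08, or 1.06 with normexp. The shift of the list against all other genes was 0.23, and 0.14 without a filter. Of 9 measured metallothionein and zinc export genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone), with a mean of 0.54, or -0.23 with scaling to the spike-ins (adjusted p = 0.0073, and adjusted p = 0.411 with an estimated correlation). These were MT1X (0.73 ± 0.11), MT1A (0.71 ± 0.13), MT1L, MT1E and, outside the naming rule, MT1B, whose probes can bind each other's RNA. The shift of the list against all other genes was 0.51, and 0.33 without a filter, and a second MT1E probe gave 0.076. The call of MT1L was lost without CSC replicate 2 (adjusted p = 0.0504) or DMSO replicate 1 (0.0522), and that of MT1E without CSC replicate 1 (0.0505) or DMSO replicate 1 (0.0584), with 0.0045 and 0.0047 as the lowest over 16 alternatives. Among 18 measured cytosolic heat shock genes 2 rose and 0 fell (2 and 0 adjusted over the list alone, as at an unadjusted p under 0.05), with the small heat shock protein gene CRYAB at 0.88 ± 0.08. That list did not shift (adjusted p = 0.459), with a mean of 0.13 and a median of -0.0017.

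Nearly all measured genes of the ATF4 amino acid response rose, 24 of 26 with 0 falling (24 and 0 adjusted over the list alone), with a mean of 1.05, or 0.28 with scaling to the spike-ins (adjusted p = 2.8e-14, and adjusted p = 0.102 with an estimated correlation). The asparagine synthetase gene ASNS rose by 2.15 ± 0.08 (4.45-fold), SLC7A11 by 2.01 ± 0.08, the serine synthesis gene PSAT1 by 1.75 ± 0.09 and the stress-induced nuclear protein gene NUPR1 by 1.73 ± 0.10. A second ASNS probe gave 0.50 and the mean of both 1.33. The list mean was 0.91, 1.19 and 1.05 on slides 1 to 3. Of 19 measured endoplasmic reticulum chaperone genes 4 rose and 5 fell (4 and 8 adjusted over the list alone), with the folding cochaperone gene DNAJB9 at 0.90 ± 0.12 and the main chaperone gene HSPA5 at -0.64 ± 0.10, and the list did not shift (adjusted p = 0.315). It passed with normexp (adjusted p = 0.0328, up to 0.508 over 16 alternatives). Of 28 measured p53 targets, 13 rose and 2 fell (14 and 3 adjusted over the list alone), with a mean of 0.39, or -0.38 with scaling to the spike-ins (adjusted p = 0.0066, and adjusted p = 0.236 with an estimated correlation). GDF15, a secreted stress cytokine, rose by 2.85 ± 0.10 (7.21-fold), the kinase gene PLK3 by 1.07 ± 0.10, the cyclin-dependent kinase inhibitor gene CDKN1A by 1.26 ± 0.21 and the antiproliferative gene BTG2 by 0.68 ± 0.08. DDB2, a DNA damage recognition gene, fell by 0.75 ± 0.07, and CCNG1, a cyclin outside the naming rule, had a value of -0.42. The call of the p53 list was lost with normexp (adjusted p = 0.0706, from 0.0016 over 16 alternatives).

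All 36 measured mitosis genes fell (36 adjusted over the list alone). Their mean was -1.58 (adjusted p = 3.2e-30, and adjusted p = 0.0988 with an estimated correlation). The centromeric histone gene CENPA fell by 2.06 ± 0.08 (4.18-fold), the cyclin gene CCNB2 by 1.74 ± 0.08, the spindle gene DLGAP5 by 1.90 ± 0.10 and the proliferation marker MKI67 by 1.63 ± 0.16 (3.11-fold, adjusted p = 0.0011). The list mean was -1.53, -1.65 and -1.57 on slides 1 to 3. All 38 measured genes of DNA replication and S phase fell (38 adjusted over the list alone). Their mean was -1.14 (adjusted p = 3.5e-26, and adjusted p = 0.0880 with an estimated correlation). TYMS, the thymidylate synthase gene, fell by 1.37 ± 0.09, the replicative helicase genes GINS4 by 1.38 ± 0.09 and MCM7 by 1.23 ± 0.08. Of 29 measured homologous recombination and Fanconi genes, 25 fell and 0 rose (26 and 1 adjusted over the list alone). Their mean was -0.89 (adjusted p = 1.9e-15, and adjusted p = 0.146 with an estimated correlation). The helicase gene BLM fell by 1.59 ± 0.11 and MND1 by 1.62 ± 0.11.

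Of 23 measured genes of mismatch and base excision repair, 8 fell and 1 rose (9 and 4 adjusted over the list alone). Their mean was -0.24 (adjusted p = 0.0098, and adjusted p = 0.205 with an estimated correlation). The poly(ADP-ribose) polymerase gene PARP1 fell by 0.83 ± 0.08 and the glycosylase gene NEIL3 by 1.55 ± 0.20 (0.56 with normexp), while MLH3, outside the naming rule, had a value of 0.46. In nucleotide excision repair 4 of 26 measured genes fell and 0 rose (4 and 0 adjusted over the list alone), among them RPA3 (-1.41 ± 0.13) and RPA1 (-0.64 ± 0.09), subunits of the single-strand binding protein that also serves replication, and the list did not pass (adjusted p = 0.0591). It passed without DMSO replicate 1 (adjusted p = 0.0373) or DMSO replicate 2 (0.0434), as well as with 4 other settings, and its adjusted p ran from 0.0018 to 0.170 over 16 alternatives. Of 15 measured telomere protein genes 2 rose and 1 fell (4 and 2 adjusted over the list alone). The list did not shift by camera (adjusted p = 0.672), with a mean of 0.065, whereas fry pointed upward (adjusted p = 9.8e-06).

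Of 43 measured genes of collagens and matrix assembly, 23 fell and 1 rose (25 and 3 adjusted over the list alone). Their mean was -0.55 (adjusted p = 4.3e-08, and adjusted p = 0.125 with an estimated correlation). Periostin (POSTN) fell by 2.70 ± 0.08 (6.50-fold), COL3A1 by 2.50 ± 0.16 (5.64-fold), COL8A1 by 1.71 ± 0.09, COL6A1 by 1.39 ± 0.08 and COL1A1 by 0.92 ± 0.09 (1.89-fold, adjusted p = 0.0014). FMOD, the collagen-binding proteoglycan fibromodulin and the member that rose, had a value of 1.39. Of 34 measured genes with a COL symbol, 15 fell and 3 rose, and the rises, outside the list and chosen after their values were seen, were COL4A6 (2.90 ± 0.12), COL4A5 (0.86 ± 0.11) and COL24A1 (0.47 ± 0.09, negative with scaling to the spike-ins). Of 18 measured fibroblast markers 8 fell and 2 rose (8 and 2 adjusted over the list alone). Their mean was -0.31 (adjusted p = 0.0073, and adjusted p = 0.125 with an estimated correlation). They include decorin (DCN, -1.50 ± 0.10), the fibroblast activation protein gene FAP (-1.28 ± 0.10) and LUM (-0.85 ± 0.09), with the transcription factor genes TCF21 (0.99) and TBX5 (0.42) as the rises, and the list missed the threshold on scan day 1 alone (adjusted p = 0.0512, from 0.00013 over 16 alternatives).

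Of 17 measured metalloproteinase and inhibitor genes, 9 rose and 1 fell (11 and 1 adjusted over the list alone), with a mean of 0.61, or -0.16 with scaling to the spike-ins (adjusted p = 0.0016, and adjusted p = 0.0988 with an estimated correlation). The stromelysin gene MMP3 rose by 4.28 ± 0.11 (19.4-fold), MMP16 by 0.98 ± 0.12, MMP2 by 0.80 ± 0.11 and the inhibitor gene TIMP1 by 0.72 ± 0.10, and MMP19, outside the naming rule, had a value of -0.55. MMP1, the interstitial collagenase gene, differed by 0.35 ± 0.11 and did not pass (adjusted p = 0.0630), but passed without CSC replicate 3 (adjusted p = 0.0418) and with 3 other settings, down to 0.0402 over 16 alternatives. In the myofibroblast and TGF-beta list 7 of 23 measured genes rose and 2 fell (7 and 3 adjusted over the list alone), with the inhibitory gene SMAD7 at 2.38 ± 0.11, PMEPA1 at 1.02 ± 0.10 and TGFBI at 0.88 ± 0.11. ACTG2, a smooth muscle actin gene, fell by 0.75 ± 0.09, and ACTA2, the myofibroblast marker alpha smooth muscle actin, differed by 0.16 ± 0.10 and did not pass (adjusted p = 0.334). The list did not shift (adjusted p = 0.0845), nor did the list of smooth and skeletal muscle markers (adjusted p = 0.0641). In the muscle list 4 of 13 measured genes fell and 0 rose (5 and 0 adjusted over the list alone). The troponin gene TNNT1 was among the falls at -1.03, or -0.54 with normexp, and kept its call. The myofibroblast list passed without CSC replicate 1 (adjusted p = 0.0482) or DMSO replicate 3 (0.0282). The muscle list passed without the same arrays (0.0459 and 0.0282) and with 2 other settings. Their highest values were 0.506 and 0.283 over 16 alternatives.

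Of 27 measured interferon-stimulated genes, 13 fell and 1 rose (15 and 1 adjusted over the list alone). Their mean was -0.61, or -0.22 with normexp (adjusted p = 4.0e-07, and adjusted p = 0.0645 with an estimated correlation). IFI44 fell by 1.37 ± 0.09 (0.85 with normexp), the antiviral GTPase gene MX1 by 1.09 ± 0.09 and IFIT1 by 1.19 ± 0.11, while OASL, outside the naming rule, had a value of 0.65. Of 21 measured NF-kB targets, 9 fell and 2 rose (11 and 2 adjusted over the list alone). Their mean was -0.52 (adjusted p = 0.0010, and adjusted p = 0.230 with an estimated correlation). The chemokine genes CXCL1 (-2.63 ± 0.10, 6.19-fold), CCL2 (-2.34 ± 0.13) and CXCL3 (-1.57 ± 0.11, or -1.01 with normexp) fell, and the rises, outside the naming rule, were the cyclooxygenase gene PTGS2 (1.82) and the complement gene C3 (0.49). IL6 differed by -0.15 ± 0.17 and did not pass (adjusted p = 0.618). Of 30 measured secretory factors associated with senescence, 10 rose and 12 fell (12 and 13 adjusted over the list alone), with MMP3, GDF15 and ANGPTL4 among the rises and CXCL1 and CCL2 among the falls. Of the 33 factors listed, 16 are also in other lists, so these counts repeat genes given elsewhere. That list did not shift by camera (adjusted p = 0.586), with a mean of -0.042, whereas fry gave a balance upward (adjusted p = 0.0059), and camera gave 0.224 to 0.917 over 16 alternatives.

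Autophagy and lysosome genes rose, 18 of 31 measured with 0 falling (22 and 0 adjusted over the list alone), with a mean of 0.54, or -0.23 with scaling to the spike-ins (adjusted p = 2.6e-07, and adjusted p = 0.0880 with an estimated correlation). NPC1, the lysosomal cholesterol exporter, rose by 2.50 ± 0.14 (5.64-fold), its partner NPC2 by 0.78 ± 0.10, the autophagy receptor gene SQSTM1 by 1.54 ± 0.14 and GABARAPL1 by 0.88 ± 0.11. The list mean was 0.45, 0.62 and 0.55 on slides 1 to 3. Of 20 measured fatty acid oxidation and lipid storage genes 6 rose and 2 fell (6 and 2 adjusted over the list alone), with the lipase inhibitor gene ANGPTL4 rising 7.99-fold, FABP3 at 1.03 ± 0.11 (0.67 with normexp) and the lipid droplet coat gene PLIN2 at 0.77 ± 0.08. The list did not shift (adjusted p = 0.0840), but passed without DMSO replicate 3 (adjusted p = 0.0228, up to 0.197 over 16 alternatives). Of 24 cholesterol synthesis genes 9 rose, among them CYP51A1 (0.75 ± 0.09), and 2 fell, among them TMEM97 (-1.28 ± 0.14; 9 and 2 adjusted over the list alone), with no shift of the list (adjusted p = 0.221).

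Of 40 measured cytosolic ribosomal protein genes 0 changed by limma (0 adjusted over the list alone and 0 at an unadjusted p under 0.05), and the list did not shift (adjusted p = 0.323). It passed camera at the preset correlation without CSC replicate 3 (adjusted p = 0.0082, up to 0.921 over 16 alternatives) and on scan day 1 alone (0.0272). Its estimated correlation over all arrays was 0.78, far above the preset 0.01, and gave a camera adjusted p = 0.863. Of 45 oxidative phosphorylation genes 1 rose and 0 fell (0 and 0 adjusted over the list alone, adjusted p of the list 0.569). Of 17 glycolysis genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, adjusted p of the list 0.381). Of 30 proteasome genes 1 rose and 1 fell (0 and 0 adjusted over the list alone, adjusted p of the list 0.891, mean 0.0082, median -0.0074). The hexokinase gene HK2 rose by 0.73 ± 0.10 and the phosphofructokinase gene PFKP fell by 0.54 ± 0.08. Of 17 hypoxia response genes 4 rose and 3 fell (5 and 4 adjusted over the list alone, adjusted p of the list 0.771), with NDRG1 at 1.03 ± 0.09 and MXI1 at 1.21 ± 0.16. Among markers of other cell types, 1 of 7 endothelial genes rose and 2 fell (1 and 2 adjusted over the list alone, adjusted p of the list 0.758). Of 14 epithelial genes 1 rose, the tight junction gene CLDN4 (1.59 ± 0.09), and 1 fell, the keratin gene KRT19 (-0.87 ± 0.09; 1 and 1 adjusted over the list alone), and the list did not shift (adjusted p = 0.954), its mean of 0.093 being opposite in sign to the camera statistic.

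**Figure D2:**
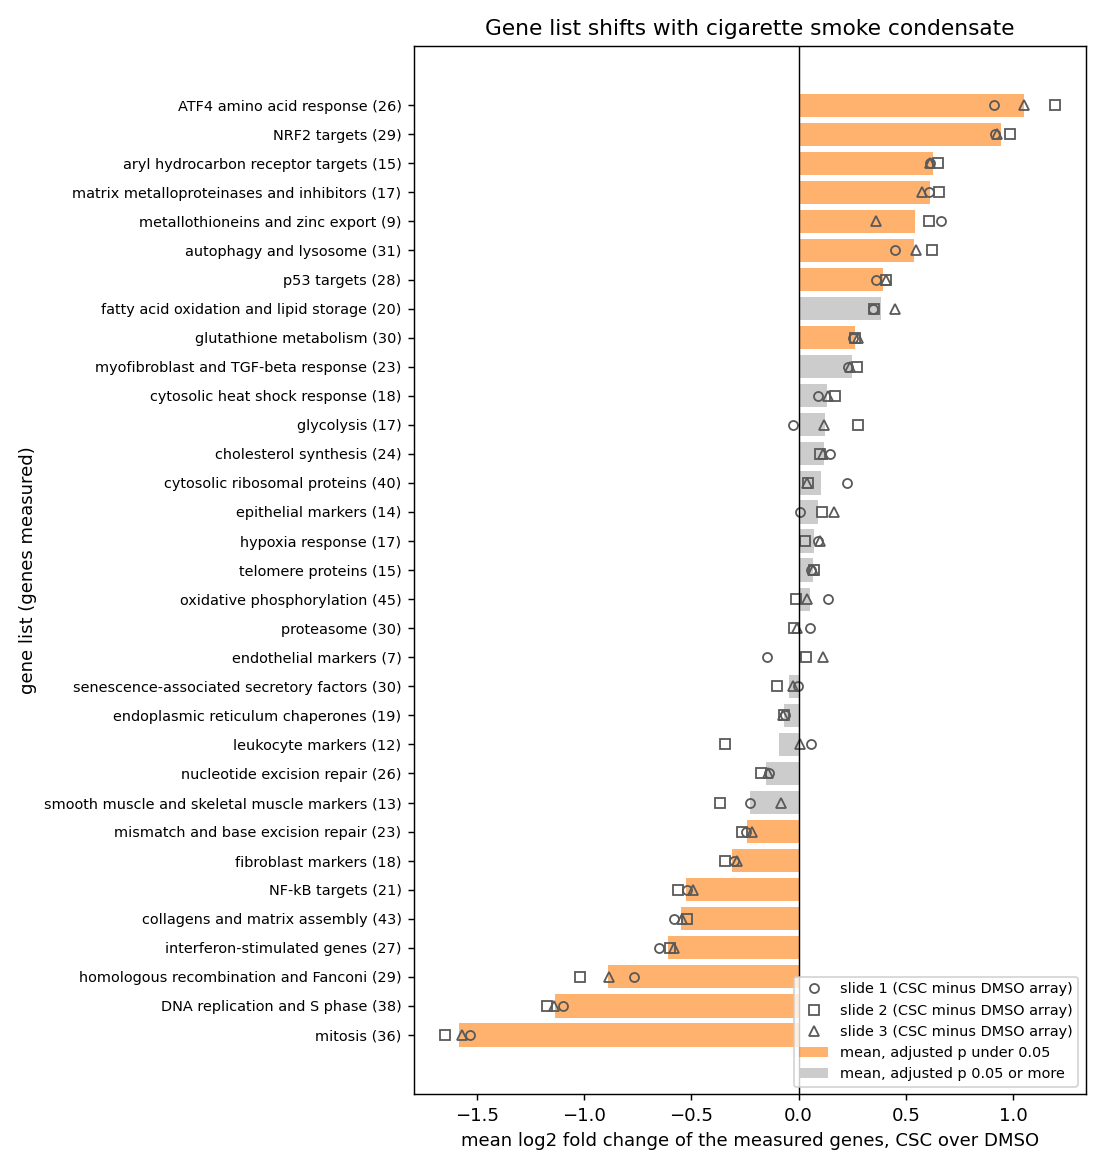
Mean log2 fold change (CSC over DMSO, x axis) of the measured genes of each of 33 gene lists (y axis, number of genes in brackets), with bars for the mean over 3 arrays per group, orange where the camera adjusted p was under 0.05, and open symbols for the CSC minus DMSO difference on each of the 3 slides. The 16 orange lists have the same sign on all 3 slides, from -1.58 for mitosis to 1.05 for the ATF4 amino acid response, and 6 of the 8 upward lists turn negative with scaling to the spike-ins.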

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

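Spike-in scaling and the use of scan day 1 alone were chosen only after the results were seen. The number of genes changed with CSC, 4873 in the main setting, was 2868 without DMSO replicate 2, 2821 with normexp (1576 higher, 1245 lower), 3004 with median scaling (1210 higher and 1794 lower), 1291 with a 2-fold minimum (624 higher, 667 lower), 2493 at a threshold of 0.01 (1275 higher, 1218 lower) and 8446 with spike-in scaling (253 higher, 8193 lower), and stayed within 1.5 times under the other alternatives run. Of genes higher with CSC scan day 1 alone gave 1621, and of genes lower with CSC 1761. Leaving out 1 array gave 2868 to 3921 changed, 1478 to 2062 higher and 1390 to 1929 lower, with fewer samples by construction. For the thresholds the construction explains the lower counts. Scaling to the array median or to the spike-ins subtracts 1 constant per array, so all fold changes move down together. The median of all genes was then -0.038 and -0.72, and the move of the split toward lower names follows by construction. For the other counts the cause was not tested. With every probe tested, 14 names called in the main setting had probes called in both directions. In the other settings no name called in the main setting was called in the opposite direction. Spike-in scaling kept 250 of the 2604 higher and all 2269 lower calls. It left a positive fold change in 971 of the 2604, and the others turned negative, among them BTG2, TIMP1, CYP51A1, HK2, CD14, CD68, MT1X, MT1A, MT1L and MT1E with values from -0.021 to -0.13. HMOX1 (0.022), PLIN2 (0.00096), NPC2 (0.0046) and MMP2 (0.030) stayed positive but close to no change. Of the genes chosen after their values were seen, TBX5, C3, OASL, MLH3, MT1B and COL24A1 turned negative too. With the replicate block 4943 names changed, keeping 2257 higher and 2010 lower calls, the same 16 lists passed, and of 153 named genes 6 lost their call and 1 gained one. None of these 7 genes is named in the text, and the block changed no other call of a list or named gene.

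Of the list calls, 1 held with an estimated correlation. Fry called 26 lists, including each that passed camera. Among the rest, the telomere, fatty acid, myofibroblast, cholesterol, heat shock and hypoxia lists pointed upward by fry. The endoplasmic reticulum chaperone (fry adjusted p = 0.00041), nucleotide excision repair and muscle lists pointed downward. Over 594 list alternatives, which do not include spike-in scaling, 551 kept their side of the threshold without a called change of sign (26 uncalled ones changed sign), 17 lost and 25 gained a call, and 1 turned: the senescence-associated secretory factors, at -0.076 against all other genes, pointed upward by fry (adjusted p = 0.0059). Over 2430 alternatives of the named genes, also without spike-in scaling, 2291 did so (5 uncalled ones changed sign), 124 lost and 14 gained a call, and MYOCD turned to 0.040 with normexp. The lowest pair correlation of slide deviations, 0.16, was 0.19 without a filter and 0.19 with quantile normalization. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many changed names with limma, the real one with 4873, and the highest of the others gave 0 (202 to 1541 at an unadjusted p under 0.05, against 7216). With 10 splits no share under 0.05 can be reached. Dim genes rest on arrays near background, and their folds shrink most with normexp.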

Other observations

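The search over gene families, the genes named from it and both spike-in tests were chosen only after the results were seen. Among 236 families of gene symbols with at least 8 measured members, 12 shifted by limma's camera after Benjamini-Hochberg adjustment, and 0 did with an estimated correlation, where the adjusted p of each family named here was at least 0.834. Centrosomal protein genes (CEP) were lower, with 19 of 40 falling and 2 rising and a mean of -0.36 (adjusted p = 0.00019). CEP55, of the final step of cell division, fell by 1.70, and CEP152, of centriole duplication, by 0.98. Nucleoporin genes (NUP) were lower too, with 9 of 21 falling and 0 rising and a mean of -0.35 (adjusted p = 0.0011), among them NUP107 (-1.02). Of 31 kinesin genes (KIF) 13 fell and 1 rose, with a mean of -0.53 (adjusted p = 0.0045). The falls include the mitotic kinesins KIF2C (-1.86) and KIF15 (-1.95), and the rise was KIF26B (1.53, with 1 of 3 DMSO arrays well above background). Serine- and arginine-rich splicing factor genes (SRSF) had a mean of -0.48 (adjusted p = 0.011), with 5 of 12 falling, among them SRSF1 (-1.06), and 0 rising. In the other direction, 6 of 14 Kruppel-like factor genes (KLF) rose and 0 fell, with a mean of 0.50, or -0.27 with scaling to the spike-ins (adjusted p = 0.011). KLF2 rose by 1.90, KLF11 by 1.22 and KLF4 by 1.14.

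The rise of the autophagy and lysosome list was followed up with 44 further lysosome genes, none of them in the fixed lists, written down before their values were seen. A rise of lysosome genes beyond those listed was the hypothesis, and 23 of the 41 measured (56.1%) rose and 2 fell, above the share of at least 50% set beforehand, with a mean of 0.36, or -0.41 with scaling to the spike-ins (camera p = 1.3e-06, and p = 0.0286 with an estimated correlation). Of 11 measured subunit genes of the proton pump that acidifies lysosomes 10 rose, among them ATP6V1G1 (1.09) and ATP6V0A1 (1.07), while the other 8 turn negative with scaling to the spike-ins and the subunits were not tested as a group, and the ceramidase gene ASAH1 rose by 0.88 and the mannosidase gene MANBA by 0.96. The cathepsin gene CTSC (-0.80) and the lipase gene LIPA (-0.49) fell. These values are consistent with a broad lysosomal response, a hypothesis found and tested on the same arrays, for which no technical explanation was tested.

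CCL3, SPP1 and GPNMB, which macrophages express strongly, were among the largest rises. RNA from macrophages in the CSC cultures would bring the other abundant transcripts of these cells, and 18 such genes on the array were listed. Those outside the fixed lists were written down before their values were seen. The other 7 are also in the fixed lists, which had been tested by then, so they are no independent check. The 10 measured include 8 well above background on all DMSO arrays, and 0% of them rose and 0 fell by limma (0 and 1 at an unadjusted p under 0.05), while the other 8 were too dim to be tested. In signals not scaled between arrays, CD74 and HLA-DRA had means of 3.59 and 2.13 on the CSC arrays and were well above background on none of them. TYROBP had an unscaled 77.0 with CSC against 135 with DMSO, but its scaled difference of -0.33 ± 0.18 did not pass (limma adjusted p = 0.252). LAPTM5 (11.7 against 2.83) and CD163 (4.27 against 1.94), also unscaled, were brighter with CSC and above background on 1 CSC array each. CD14 (0.68) and CD68 (0.69), outside these 18, rose with CSC. The 8 measured genes with signal on all DMSO arrays could hide a small addition, so they decide little. By the levels of CD74 and HLA-DRA, in samples titled as MRC5 cells, macrophage RNA is unlikely as the whole source of the rises. An effect of CSC on the fibroblasts stays open.

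Against 7 spike-in transcripts, the 75th percentile of gene signal was lower on the CSC arrays by a log2 difference of -0.77 ± 0.22 (SE), with -0.85, -1.07 and -0.39 on slides 1 to 3 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). Lower labelling or hybridization of the CSC arrays as a whole would lower spike-ins and genes alike and leave their ratio at 0, whereas the raw signal of the spike-ins was higher with CSC on slides 1 to 3, by 0.27, 0.49 and 0.11, and that of the genes differed by -0.48. Together with the ratio, this argues against it as the whole cause. Unequal amounts of spike-in mix or of total RNA would shift all spike-ins together against the genes, and they did, with a standard deviation over the 7 of 0.072 around that shift. A lower share of messenger RNA in total RNA with CSC predicts the same, so these cannot be told apart, and neither can an effect of array position.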
